A study of Mus musculus with 6 samples.

How the data were processed

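The submitters' processing notes name FastQC, a quality check of reads, and HISAT2, an aligner, without versions. The genome build, the annotation and the program that made the counts are not given in the sources used here. Per the file headers and values, each sample has a deposited table of estimated counts per gene and a table of TPM, which scale counts by gene length and library total, both made by the authors. From 23.5 to 25.2% of genes in each library had counts that were not whole numbers. The TPM columns sum to between 999992 and 1000008 over the listed genes and were used for alternative settings.

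Each table listed 21899 genes, of which 4430 were at 0 in every sample. Ensembl identifiers in the tables were matched to GENCODE M21 (GRCm38), a reference that need not be the authors' own, for positions and gene types. A match was found for 21806 identifiers and not for 93. The expected counts were rounded to whole numbers first. Genes were kept by edgeR's filterByExpr at its defaults (12768 kept, 9131 not kept), and libraries were scaled by TMM, with factors from 0.988 to 1.01. KO was compared with WT by the two-sided quasi-likelihood F test of edgeR 4.0.16 with robust dispersion, with genotype as the single term. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the threshold. CPM values are TMM-scaled, and log2 fold changes are KO minus WT with the model's standard errors.

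The test, the samples, 39 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Gene lists with 5 or more tested members, 37 of them, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and beside it with camera at an estimated correlation and with fry. Both camera and fry are models across genes. The symbols Eos, Cd103 and Ahsp of the lists were not matched. Some genes stand in more than 1 list, such as Btla and Fcgr3.

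Named by rule were Dlst and Foxp3, Ogdh, Dld, Stub1 and Usp7, and the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean log2 CPM of at least 2 and no overlap between groups (37 and 20 qualified). In each list the rule took up to 4 members past the threshold, or up to 2 of the smallest p where none passed. S100a8, S100a9, Ngp, Lyz2, Cd8a, Cd3e, Cd4, Ddx3y, Eif2s3y, Myh6, Esd, Rdh12, Pcx and Gclm were chosen after their values were seen. Results of some genes that the rule takes are not reported here. Counting intervals come from an exact Poisson comparison of summed counts, at 95%, and cover counting error only.

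The methods were tried on 12768 simulated genes with 50 changed genes at each size. The edgeR test recovered 6% of 1.2-fold, 64% of 1.5-fold, 76% of 2-fold and 92% of 4-fold changes, with 15 false calls of 134, and made 0 calls where nothing was changed. DESeq2 made 41 false calls of 170, and 18 calls where nothing was changed. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.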

Results

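Induced regulatory T cells (iTregs) were profiled by bulk mRNA sequencing from 6 samples, 3 from control mice (WT) and 3 from mice in which Dlst can be deleted in Treg cells (KO). Dlst encodes the E2 subunit of the 2-oxoglutarate dehydrogenase complex, the TCA cycle enzyme that makes succinyl-CoA. Splenic CD4+ T cells were polarised for 2 days with 4-hydroxytamoxifen, the drug that activates tamoxifen-inducible Cre recombinase, and cells positive for CD4, a FoxP3-GFP reporter and tdTomato were sorted. Libraries held 35647816, 47526481 and 46359646 estimated counts in WT and 49772670, 33590510 and 39049039 in KO. Of 21899 listed genes, 12768 had enough counts to be tested. Nothing in the labels says that the samples came from separate animals or cultures, so the p-values measure the spread between these samples, which may in part be technical. Y-linked mRNAs set KO replicate 1 apart from the other 5 samples in its source. The comparison asked what loss of Dlst does to the transcriptome of these cells.

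Dlst mRNA was lower in all 3 KO samples than in all 3 WT samples, but most of it was still present. Its level was 161, 149 and 149 CPM (counts scaled to library size) in WT replicates 1 to 3 and 125, 129 and 129 CPM in KO replicates 1 to 3. The means were 153 ± 6.86 CPM in WT and 128 ± 2.33 CPM in KO (SD, n = 3 each). The Dlst log2 fold change was -0.26 (SE 0.05, 95% interval -0.38 to -0.14). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes the adjusted p was 0.0894, so Dlst did not pass the threshold of 0.05. DESeq2 gave an adjusted p of 0.00182, against 0.0323 to 0.28 under the other alternatives. Dlst (ENSMUSG00000004789) lies on the plus strand of chromosome 12 from 85110833 to 85134845 in GENCODE M21 (GRCm38). The value covers the whole gene, and levels of the deleted exons alone were not analysed here. The other subunit genes did not pass: Ogdh (E1) had a log2 fold change of -0.07 (SE 0.08, adjusted p = 0.707 by edgeR) and Dld (E3) of -0.00 (SE 0.07, adjusted p = 0.984), and both signs turned under some settings.

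Foxp3, the Treg-defining transcription factor whose reporter was sorted, had a mean of 185 ± 26.5 CPM in WT and 222 ± 13.2 CPM in KO (SD, n = 3 each). Each KO sample lay above each WT sample, but the log2 fold change of 0.26 (SE 0.11) did not pass (edgeR adjusted p = 0.305). The genes of the FoxP3 protein stability and acetylation list had a median log2 fold change of 0.01 (camera adjusted p = 0.795): 0 of 25 tested members passed over all genes, and 1, Rnf128, rose adjusted over the list alone. Stub1, a ubiquitin ligase, stood at a log2 fold change of 0.03 (SE 0.07) and Usp7, a deubiquitinase, at 0.01 (SE 0.05), with edgeR adjusted p of 0.861 and 0.95, and both signs turned under some settings. Rnf128, another ubiquitin ligase expressed at 0.65 CPM in WT and 2.1 CPM in KO, was at 1.70 (SE 0.33, adjusted p = 0.083 by edgeR). Rnf128 was highest in KO replicate 1, at 2.92 CPM against 1.67 and 1.70 CPM in the other KO samples. The neutrophil and monocyte genes described below were highest there too, and whether Rnf128 follows other cell types was not tested.

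Across all tested genes 58 were higher and 28 lower in KO. The 58 include Prss34 and Itgax, of the marker lists of other cell types described below. They also include genes that were very low in WT, such as C3ar1 (0.07 CPM in WT and 1.10 CPM in KO) and Mrc1 (0.20 and 1.05 CPM). How many of the 58 follow the level of other cell types was not tested, so the count cannot be read as a response of Treg cells alone. Myh7, a heart myosin gene on chromosome 14, had the largest fall of the genes named by rule, with 1652 counts over the 3 WT libraries and 5 over the 3 KO libraries, 312-fold more in WT per library size (95% interval 134 to 963, counting error only). Its neighbour Myh6 had 362 counts in WT and 1 in KO, 342-fold more in WT (95% interval 61 to 13500). The next largest falls of the genes named by rule, which asks for a mean log2 CPM of at least 2, were Lamc3, a laminin chain, at a log2 fold change of -1.55 (SE 0.20), Dynlt1b at -1.39 (SE 0.13), Stau2 at -1.30 (SE 0.17), Gpm6b at -1.18 (SE 0.17) and Crat, carnitine acetyltransferase, at -1.00 (SE 0.11). On that scale Penk, the enkephalin precursor, was at -0.96, Sfn at -0.90 and Syn1 at -0.84.

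Among called genes with a mean log2 CPM of at least 2 the largest rises were Gm16867 at 3.70 (SE 0.21), Lpl, lipoprotein lipase, at 3.33 (SE 0.34), Hmgn2-ps at 1.87 (SE 0.06), Il17a at 1.85 (SE 0.26) and Spp1, osteopontin, at 1.82 (SE 0.19). Epb41l1 followed at 1.69, Csf2rb2 at 1.65, Ccl9 at 1.42, Tspan9 at 1.38 and Smim8 at 1.10. Esd rose by 0.91. Several of these were highest in KO replicate 1, the library in which neutrophil and monocyte genes were also highest: Lpl was at 19.8 CPM there against 9.92 and 10.0 CPM in the other KO samples. Likewise Spp1 was at 16.1 against 11.1 and 12.3 CPM, Csf2rb2 at 14.2 against 9.53 and 9.86 CPM, and Ccl9 at 10.3 against 7.44 and 6.67 CPM. Of the 86 called genes 47 had whole-number counts in every library. The others, among them Myh6, Myh7, Gm16867, Hmgn2-ps, Dynlt1b, Epb41l1, Crat, Lpl, Csf2rb2, Ccl9, Bcl2, Scd1 and Itgax, had counts with decimals in at least 1 library, and the levels of those with near-identical or overlapping genes, such as Myh6, Myh7, Gm16867, Hmgn2-ps and Dynlt1b, are uncertain.

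These calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, and 1924 genes had an unadjusted p under 0.05. All 86 called genes had no overlap between the WT and KO samples, which held for 22.8% of tested genes against 10% by chance. The number of calls rested on single libraries: 27 genes were called without WT replicate 2, 16 without WT replicate 3, 10 without KO replicate 2 and 4 without KO replicate 3, against 93 without WT replicate 1 and 82 without KO replicate 1. Esd, Myh7, Hmgn2-ps and Gm16867 were called in each of these 6 fits and were the 4 called without KO replicate 3. Of these, Esd, Myh7 and Gm16867 lie on chromosome 14, which held more calls than expected, as described below. Myh7, Hmgn2-ps and Gm16867 are among the genes with decimal counts and uncertain levels. As a check chosen after seeing the data, 8 genes were called when KO replicates 2 and 3, whose biological coefficient of variation was 2.9% against 6.7 to 12.1% in the other pairs within a group, were summed as 1 library.

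**Figure D1:**
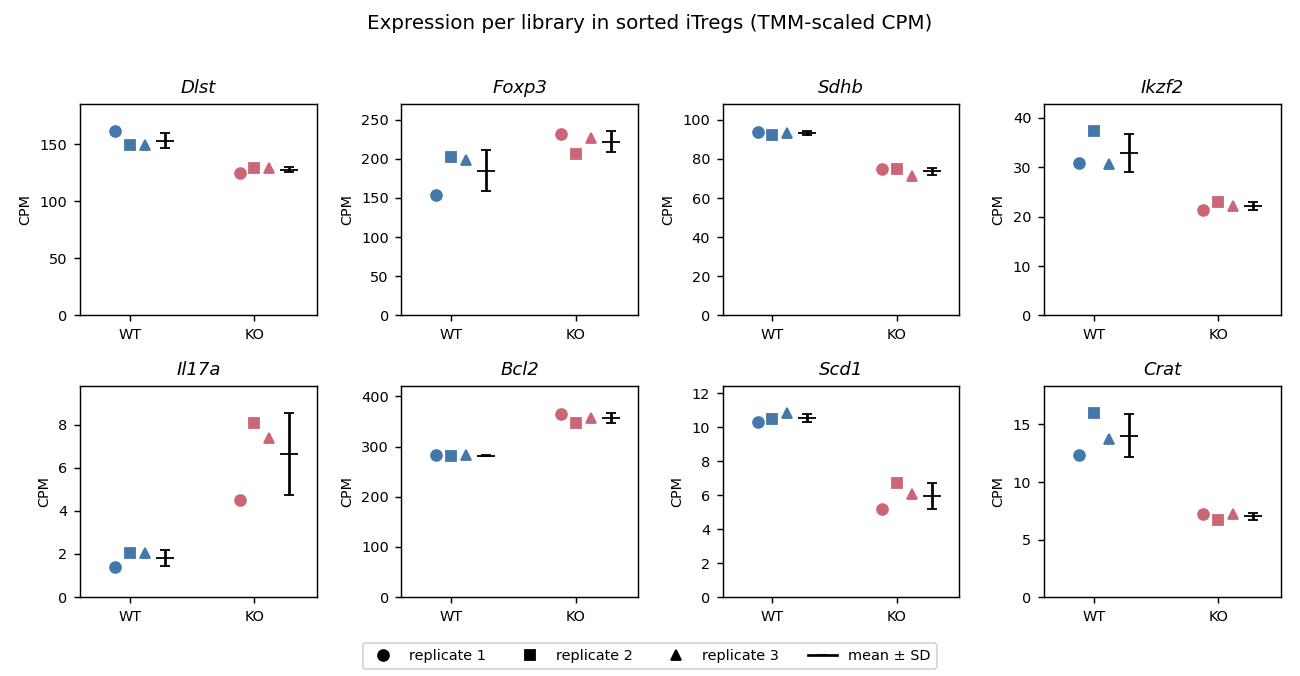
TMM-scaled CPM of 8 genes in each library, with WT samples in blue and KO samples in red, replicates by symbol, and the mean ± SD of 3 samples as a black bar on axes that start at 0. Dlst, Sdhb, Ikzf2, Scd1 and Crat are lower in each KO sample than in each WT sample, Il17a and Bcl2 are higher, and Foxp3 runs from 154 to 202 CPM in WT and from 207 to 231 CPM in KO.

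Among metabolic genes, Sdhb, the iron-sulphur subunit of succinate dehydrogenase, fell from 93.1 ± 0.911 CPM in WT to 73.7 ± 1.95 CPM in KO (SD, n = 3 each). Its log2 fold change was -0.34 (SE 0.05) and its edgeR adjusted p 0.0292. Sdhb starts at 140961203 on chromosome 4, close to another called gene, Padi2, which ends at 140952586. Padi2 was also lower in KO (log2 fold change -0.62, edgeR adjusted p = 0.0124). Whether the fall of Sdhb reflects its place on the chromosome cannot be told here, as for the other neighbouring calls below. Sdhb was the 1 member of 24 in the list of the OGDH complex and TCA cycle that fell over all genes, with 0 that rose and 23 that did not pass, and 3 fell adjusted over the list alone, Sdhb, Dlst and Pcx. Dlst, the gene targeted for deletion, is itself a member, and the list was not tested without it. The list's median log2 fold change was -0.05, and camera with a preset correlation put it lower (adjusted p = 0.0308). It had an adjusted p = 0.741 with an estimated correlation, 0.219 without KO replicate 1 and 0.299 without WT replicate 1, where the median was -0.02 in each case, and 0.0553 with a replicate block. Without both of these replicates the median was 0.01 (0.78). Scd1, a fatty acid desaturase, fell by 0.82 (edgeR adjusted p = 0.0301), the 1 member of 18 to fall in the list of fatty acid synthesis and oxidation, where 0 rose. Adjusted over the list alone 1 rose and 3 fell, and the list did not pass camera (adjusted p = 0.256).

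No member of the other metabolic and stress lists passed over all genes. Cholesterol and sterol synthesis had a median of -0.10 over 19 tested members (camera adjusted p = 0.0128, adjusted p = 0.741 with an estimated correlation). Srebf2, a regulator of sterol synthesis, stood at -0.14, and the call was lost without KO replicate 1 (0.0559) or WT replicate 2 (0.168). Glycolysis and lactate transport had a median of -0.14 over 21 members (0.0409, and adjusted p = 0.756 with an estimated correlation). It had Hk1 at -0.20 and Slc2a1 at -0.37, and lost its call without KO replicate 1 (0.508) or WT replicate 1 (0.733), where its median turned to 0.015, with a replicate block (0.0652) and with the stricter filter (0.0526). Without KO replicate 1 and WT replicate 1 together, a setting chosen after seeing the data, it passed as higher in KO (median 0.07, 0.0108). The mitochondrial unfolded protein response list had a median of -0.11 over 15 members (0.0251, and adjusted p = 0.741 with an estimated correlation). The Pink1 log2 fold change was -0.71 (SE 0.15), past the threshold adjusted over the list alone, and over all genes without KO replicate 1 (-0.92, edgeR adjusted p = 0.00387, against 7.87e-05 to 0.288 over all settings). Pink1 starts at 138313409 on chromosome 4, in the region of Padi2 (start 140906344) and Sdhb, which were also lower. Whether its fall reflects its place on the chromosome cannot be told here. The list's call was lost without KO replicate 1 (median -0.05, 0.12) or WT replicate 1 (-0.06, 0.263). The ATF4 and integrated stress response list had a median of -0.06 over 29 members (0.0401, and adjusted p = 0.741 with an estimated correlation). The Slc7a11 log2 fold change went the other way at 0.96, or 0.505 without KO replicate 1, and the list's call was lost without KO replicate 1 (median -0.01, 0.476), WT replicate 2 (0.168) or WT replicate 3 (0.0502), with no low-count filter (0.0597) and with the stricter filter (0.0526).

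The list of NRF2 targets and glutathione genes was higher in KO, with a median log2 fold change of 0.15 over 19 tested members, 14 of them above 0. Hmox1, heme oxygenase, which macrophages also express, stood at 0.67 (SE 0.14) and Gclc, of glutathione synthesis, at 0.23 (SE 0.05). None of the 19 passed over all genes, and Hmox1, Gclc and Gclm rose adjusted over the list alone. Hmox1 was highest in KO replicate 1 (29.8 CPM, against 22.7 and 27.1 CPM in the other KO samples). The macrophage and neutrophil markers, whose medians in KO were 0.92 and 3.36 above WT, were also highest there. Camera gave an adjusted p = 0.00142, and adjusted p = 0.309 with an estimated correlation. With the preset correlation the list also passed without KO replicate 1 (median 0.137, 0.00233) and without WT replicate 1 (median 0.143, 0.00119). The fry test, which tests whether a list moves one way without comparing it with other genes, gave an adjusted p of 0.0143, the 1 list of 37 that passed it. Nuclear-encoded oxidative phosphorylation (median -0.04 over 44 members, camera adjusted p = 0.0513), HIF and hypoxia targets (-0.15, 0.134), succinate and 2-oxoglutarate handling (median -0.02, mean 0.015, 0.318), 2-oxoacid dehydrogenase and lysine degradation (-0.05, 0.303), amino acid transport and mTORC1 (0.01, 0.91) and 2-oxoglutarate-dependent chromatin dioxygenases (0.03, 0.616) did not pass. Oxidative phosphorylation passed, lower in KO, without WT replicate 2 (0.00782), WT replicate 3 (0.0207) or KO replicate 2 (0.0192), and HIF targets did without WT replicate 3 (0.00599). Without WT replicate 1 their medians were -0.002 (0.684) and -0.06 (0.66), and without KO replicate 1 -0.03 (0.408) and -0.09 (0.676). Alkbh1, in the list of dioxygenases, stood at 0.32 (SE 0.06, edgeR adjusted p = 0.071), and it was the 1 member to rise adjusted over the list alone.

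Among Treg genes, Ikzf2, which encodes Helios, fell from 32.9 ± 3.77 CPM in WT to 22.1 ± 0.824 CPM in KO (SD, n = 3 each; log2 fold change -0.57, SE 0.09, edgeR adjusted p = 0.0366). It was the 1 member of 29 tested in the Treg core list to fall, over all genes and adjusted over the list alone, and 0 rose. The list as a whole had a median of -0.08 and did not pass camera (adjusted p = 0.124, with 0.0454 without WT replicate 3 and 0.492 at a median of -0.03 without WT replicate 2). Bcl2, the anti-apoptotic factor, rose from 282 ± 1.23 CPM to 357 ± 9.93 CPM (0.34, SE 0.05, adjusted p = 0.0289 by edgeR). It was the 1 of 18 members of the STAT5 and IL-2 response list to rise, with 2 up and 2 down adjusted over the list alone and a camera adjusted p = 0.303. The list passed without WT replicate 2 (median 0.15, 0.0345), against a median of 0.09 with all samples, 0.04 without KO replicate 1 (0.619) and 0.015 without WT replicate 1 (0.953, camera direction lower). The Btla log2 fold change, of an inhibitory receptor gene, was -1.32 (SE 0.21) with 101 ± 8.49 CPM in WT and 40.5 ± 12.7 CPM in KO, and did not pass (adjusted p = 0.06 by edgeR). It passed without KO replicate 1 (-1.61, adjusted p = 0.00144) and under several other settings, with adjusted p from 4.95e-11 to 0.197 over all of them. Without WT replicate 2, WT replicate 3, KO replicate 2 or KO replicate 3, none of Sdhb, Scd1, Ikzf2, Bcl2 and Il17a passed, with edgeR adjusted p from 0.0604 to 0.155. Nor did Ikzf2 without KO replicate 1 (0.0992), or Il17a and Bcl2 without WT replicate 1 (0.0583 and 0.0501).

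Il17a, the Th17 cytokine, rose from a low level, 1.83 ± 0.379 CPM in WT to 6.64 ± 1.89 CPM in KO (SD, n = 3 each; edgeR adjusted p = 0.0301). It was the 1 of 17 tested members of the Th17 list to rise, and 0 fell, over all genes and adjusted over the list alone. The list's median was -0.16 and it did not pass camera (adjusted p = 0.338). Th1 (median 0.07, adjusted p = 0.592), Th2 (-0.06, 0.82), Tfh (-0.17, 0.256), T cell activation (0.02, 0.395) and inhibitory and co-stimulatory receptors (-0.08, 0.318) did not pass camera either. Nor did type I interferon response (0.20, 0.0873), NF-kB and inflammatory cytokines (0.00, 0.97), p53 and apoptosis (-0.11, 0.134), lymphocyte migration and adhesion (-0.03, 0.795) and heat shock and immediate early genes (-0.11, 0.251). The interferon list passed, higher in KO, without WT replicate 3 (0.00112) or KO replicate 2 (0.0103), but its median was 0.07 without KO replicate 1 (0.742) and 0.12 without WT replicate 1 (0.676). No member of these lists passed over all genes. Adjusted over the list alone, Btla fell in the Tfh list and in that of inhibitory receptors, Egr3 rose and Cd5 fell in T cell activation, and Itga4 rose and Cxcr6 fell in migration. Egr3 starts at 70077203 on chromosome 14, near the called gene Entpd4b, which ends at 69585520 and was also higher in KO. Whether the rise of Egr3 reflects its place on the chromosome cannot be told here.

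All 24 tested genes of the S phase list and all 24 of the G2 and M phase list had log2 fold changes below 0, with a median of -0.18 in each, or -0.07 for S phase without WT replicate 1 and -0.11 for G2 and M phase without WT replicate 3. Cdk1 stood at -0.24 (SE 0.07), Aurkb at -0.30 (SE 0.09) and Cdc45 at -0.26 (SE 0.07). No member of either passed over all genes or adjusted over the list alone. Camera put both lists lower (adjusted p = 1.85e-06 and 3.77e-07), with an adjusted p = 0.741 with an estimated correlation for each, and S phase did not pass without KO replicate 1 and WT replicate 1 together (0.0684). Naive and quiescence genes had a median of 0.20 over 18 members, with Klf2 at 1.02 (SE 0.24) and Klf3 at 0.61 (SE 0.13). None passed over all genes, 4 rose adjusted over the list alone, and camera gave an adjusted p = 0.000499 and an adjusted p = 0.486 with an estimated correlation. Klf2 was highest in KO replicate 1, at 177 CPM against 107 and 124 CPM in the other KO samples. Klf2 starts at 72319033 on chromosome 8, close to the called gene Hmgn2-ps, which ends at 72305260 and was also higher in KO. Whether the rise of Klf2 reflects its place on the chromosome cannot be told here. Without KO replicate 1 the list's median was 0.145 (camera adjusted p = 0.000683). The TGF-beta response list had a median of 0.10 over 20 members, with Smurf2 at 0.27 and Tgfbi, also expressed by macrophages, at 2.76 (SE 0.65), or 1.87 without KO replicate 1. Camera gave an adjusted p = 0.0093, an adjusted p = 0.741 with an estimated correlation and 0.0745 without WT replicate 1, and 3 rose adjusted over the list alone. Ribosomal proteins, a list whose symbol pattern also took in 9 S6 kinase genes, had a median of 0.04 over 89 members (0.021, and adjusted p = 0.741 with an estimated correlation). The call was lost without WT replicate 1 (0.263), WT replicate 3 (0.168), KO replicate 2 (0.0786) or KO replicate 3 (0.06).

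Neutrophil and mast cell markers were higher in KO in all 12 tested members, with a median log2 fold change of 3.36 (camera adjusted p = 6.61e-09, and adjusted p = 0.309 with an estimated correlation), and a median of 2.31 without KO replicate 1 or 3.98 without WT replicate 1. Over all genes 1 rose, and 10 did adjusted over the list alone. Prss34, a mast cell and basophil protease at 0.07 CPM in WT and 0.97 CPM in KO, was the one that passed (edgeR adjusted p = 0.0193). S100a8, a neutrophil marker of this list, was at 10.1, 1.96 and 1.31 CPM in WT replicates 1 to 3 and at 93.1, 20.6 and 21.4 CPM in KO replicates 1 to 3. S100a9 and Ngp had the same order of groups, at 10.9, 2.45 and 1.33 against 113, 25.6 and 20.9 CPM and at 5.64, 1.64 and 1.12 against 53.6, 14.3 and 13.2 CPM. Macrophage, monocyte and dendritic cell markers had a median of 0.92, or 0.60 without KO replicate 1, over 16 members (camera adjusted p = 1.85e-06, and adjusted p = 0.741 with an estimated correlation). Over all genes 1 rose, Itgax at 1.60 (edgeR adjusted p = 0.0472), and 11 did adjusted over the list alone. Neither Prss34 nor Itgax passed without WT replicate 2, WT replicate 3, KO replicate 2 or KO replicate 3 (edgeR adjusted p from 0.059 to 0.165), nor Itgax without WT replicate 1 (0.0989). Lyz2, lysozyme, was at 18.4, 10.9 and 10.4 CPM in WT and 316, 74.7 and 84.4 CPM in KO, and the Lyz2 log2 fold change passed without KO replicate 1 (edgeR adjusted p = 0.016, against 6.87e-06 to 0.312 over all settings). B cell markers went the other way, with a median of -0.52 over 12 members (camera adjusted p = 0.795). Their summed level was 342 CPM in WT replicate 1 and 128 to 213 CPM in the other 5 samples, and the list passed without WT replicate 1 (median 0.41, adjusted p = 0.00214) or WT replicate 3 (0.00645, lower in KO). CD8 T cell and NK cell markers had a median of 0.42 over 9 members (0.275), with Cd8a and Cd8b1 above the WT samples in all 3 KO samples. None passed over all genes, and Cd8b1 and Fcgr3 rose adjusted over the list alone.

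KO replicate 1 stood apart from the other libraries. Its counts of the Y-linked genes Ddx3y and Eif2s3y were 4046 and 4129, against 0 or 1 in every other library. Mitochondrially encoded mRNAs took 2.76% of its counts against 1.43 to 1.70% elsewhere. That list had a median log2 fold change of 0.44 over 13 members, none past the threshold over all genes or adjusted over the list alone. It had mt-Nd3 at 0.31, and the mt-Nd2 log2 fold change was 0.44, or 0.196 without KO replicate 1 (camera adjusted p = 0.000499, and adjusted p = 0.741 with an estimated correlation), and a median of 0.10 without KO replicate 1 (0.0146) or 0.09 without WT replicate 1 as well (0.0684). Of the T cell genes, Cd3e ran from 289 to 327 CPM with overlapping groups, and Cd4 was at 506 to 522 CPM in WT and 432 to 465 CPM in KO (log2 fold change -0.19, edgeR adjusted p = 0.151). Erythroid and platelet markers and stromal and endothelial markers had too few tested members for camera, 3 and 4, of which none passed.

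**Figure D2:**
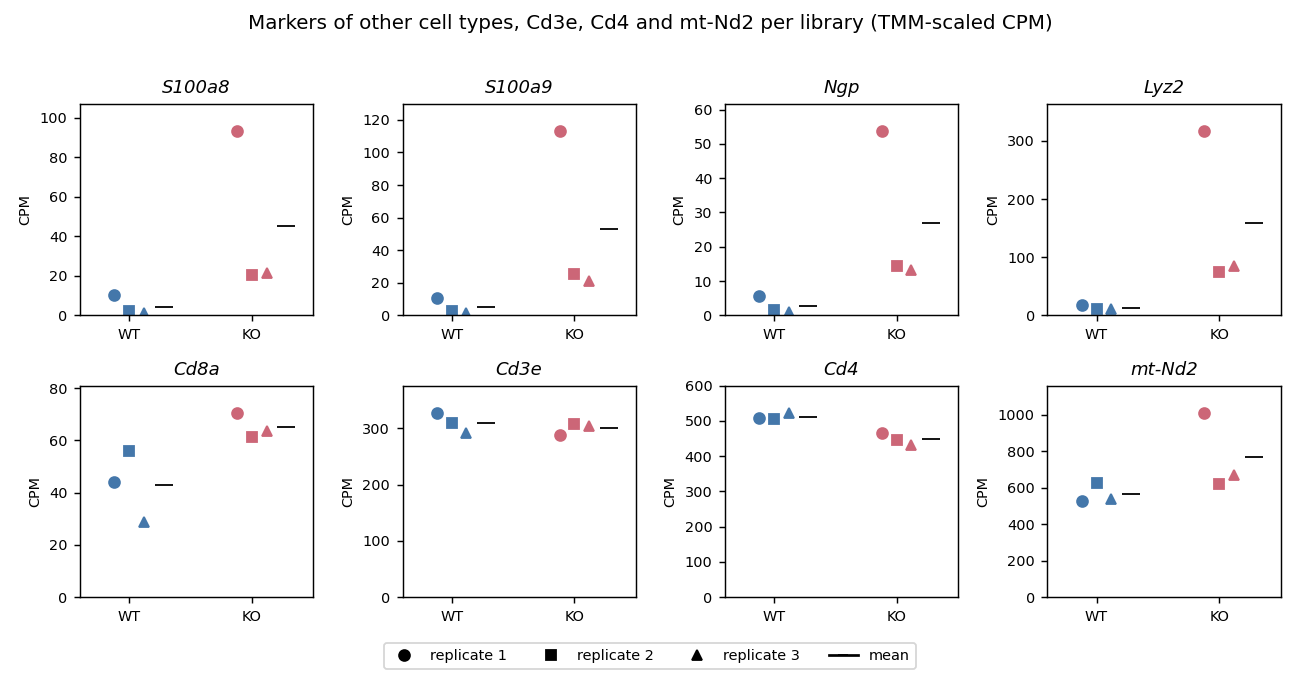
TMM-scaled CPM of markers of other cell types, the T cell genes Cd3e and Cd4 and the mitochondrial mRNA mt-Nd2 in each library, with WT in blue, KO in red, replicates by symbol and the group mean as a black line on axes that start at 0. S100a8, S100a9, Ngp and Lyz2 are higher in each KO sample than in each WT sample and highest in KO replicate 1, and Cd4 runs from 506 to 522 CPM in WT and from 432 to 465 CPM in KO.

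In all, 14 of the 37 lists tested passed camera with the preset correlation, 7 higher and 7 lower in KO. None passed with an estimated correlation, where 3 had an unadjusted p under 0.05, 9 passed without KO replicate 1, and 12 with a replicate block. Other ways of splitting the 6 samples into 2 groups of 3 passed up to 17 lists.

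**Figure D3:**
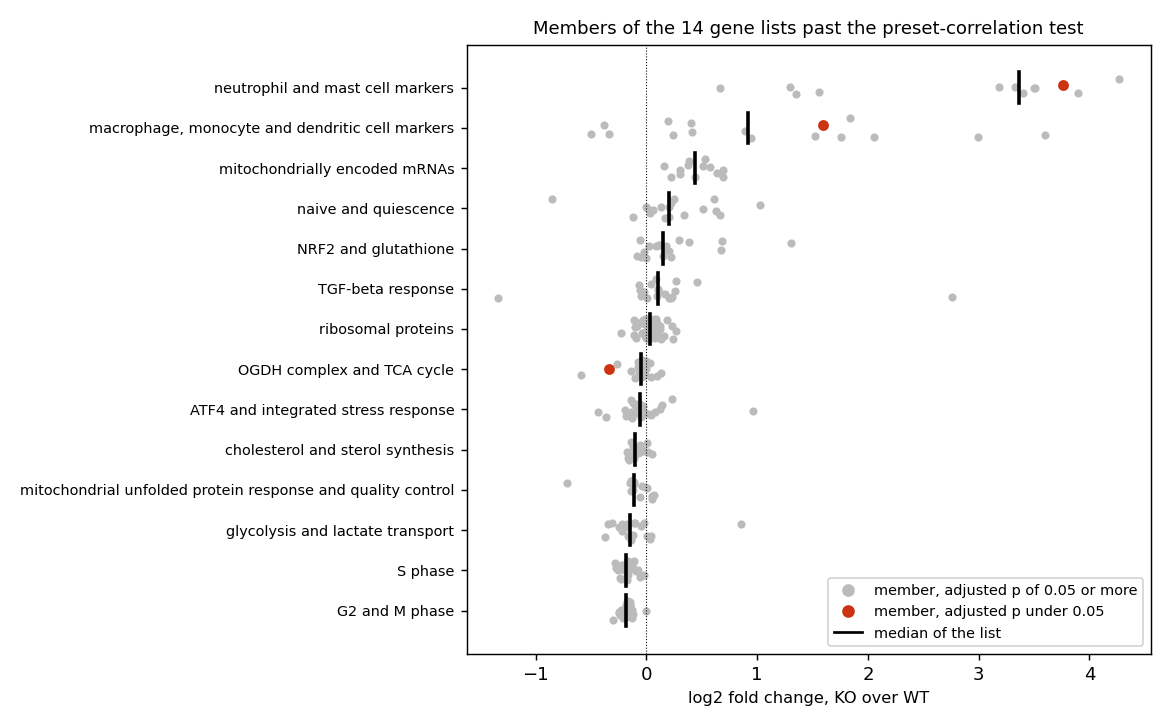
Log2 fold changes, KO over WT, of the tested members of the 14 lists that passed camera with the preset correlation, one point per gene, in red where the gene's own edgeR adjusted p was under 0.05, with a black line at each list's median. Medians run from -0.18 in the lists of S phase and of G2 and M phase to 3.36 in the list of neutrophil and mast cell markers, and Prss34, Itgax and Sdhb are the 3 members in red.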

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

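Settings with whole-number counts alone, without KO replicate 1 and WT replicate 1 together, and with KO replicates 2 and 3 summed were chosen after seeing the data. All 86 called genes kept their direction in each setting that measured them. This says little, since none of them had overlap between the WT and KO samples. Against 58 genes higher and 28 lower in KO, DESeq2's Wald test gave 366 and 161, a replicate block 134 and 43, no low-count filter 92 higher, limma on log2(TPM + 1) without a filter 4 and 1, and a fold of at least 2 left 32 and 14. Whole-number genes gave 28 and 14, a smaller set of genes. Without KO replicate 1 and WT replicate 1 together there were 311 and 227, and with KO replicates 2 and 3 summed 6 and 2. Leaving out 1 library gave 3 to 56 higher and 1 to 40 lower. Apart from the smaller gene set, fewer samples and the stricter fold, the cause was not tested. The 14 lists became 9 to 17 when 1 library was left out, 9 without KO replicate 1 and WT replicate 1 together, 1 with fry and 0 with an estimated correlation, and the cause was not tested. The Dlst log2 fold change passed with DESeq2 (-0.264) and without KO replicate 1 and WT replicate 1 together (-0.209), and Foxp3 passed in no setting (adjusted p from 0.195 to 0.549). The sign turned for Ogdh (-0.125 to 0.02 with 1 library left out, the latter without WT replicate 1, and 0.002 without both replicates 1), Dld (0.003 with upper-quartile factors, 0 with the stricter filter, -0.04 to 0.048 with 1 library left out, 0.036 without WT replicate 3, 0.048 without KO replicate 1, 0.024 without both) and Stub1 (-0.001 to 0.091, the former without WT replicate 3). It also turned for Usp7 (-0.021 to 0.028, the former without WT replicate 2, and -0.006 without KO replicate 3 and in the 3 TPM settings) and for Cd3e (0.023 without both). Whether replicate numbers pair the samples stays open. Centred profiles of equal number correlated at 0.184, 0.078 and 0.084, and those of unequal number at -0.145 to 0.112. At this depth and sample number, simulated 1.2-fold changes were mostly missed.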

Other observations

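All tests below were chosen after the result was seen, except those of whole-number genes, of the distance of 1 to 10 Mb and of the splits for lists; the reading of the neighbour tests by adjusted p and by power was also set after the results.

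Among 314 pathways of the annotation in the deposited tables with 10 to 300 tested genes, 8 passed camera with the preset correlation. DNA replication was lower in KO (median log2 fold change -0.13 over 35 genes, adjusted p = 0.00034, 0.0207 without KO replicate 1), as was the cell cycle (-0.09, 0.00333, but 0.0741 without KO replicate 1). Arginine and proline metabolism (-0.14, 0.026) and the proteasome (-0.06, 0.0311) were lower too and lost their calls without KO replicate 1 (0.12 and 0.282). Osteoclast differentiation, a pathway rich in myeloid genes, was higher (0.09, 0.0052, 0.0275 without KO replicate 1). None passed with an estimated correlation (adjusted p = 0.866 for each of these).

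Several called genes lay near one another, with 10 on chromosome 14 against 3.1 expected (Fisher's exact test, adjusted p = 0.0194). Linked genome segments that differ between the WT and KO mice may be behind this: 42 of the 86 calls had another within 5 Mb, against a median of 32 and a 95th percentile of 41 in 10000 random draws (one-sided permutation p = 0.0481, adjusted p = 0.0906 over 3 tests). Reads shared between near-identical copies may add to it: among whole-number genes 15 of 42 calls had such a neighbour (95th percentile also 15, permutation p = 0.0604), and neighbours regulated together stay open as well, with 41 calls having another 1 to 10 Mb away (95th percentile 51, permutation p = 0.542). The tests found 12.7%, 48.7% and 6% of sets with 10 planted neighbours and 29.3%, 100% and 14.7% with 20, so these explanations cannot be told apart for small clusters. Chromosome 12, which carries Dlst, held 8 calls against 2.9 expected (Fisher's exact test, adjusted p = 0.085). The call nearest to Dlst, Rdh12, lay 5.9 Mb away. Alkbh1, which did not pass (edgeR adjusted p = 0.071), lies nearer, starting at 87425840 against 85110833 for Dlst. Linked differences around Dlst therefore stay open.

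Neutrophil genes were higher in KO libraries. The sex of the mouse behind KO replicate 1 as the source is argued against by KO replicates 2 and 3, which lay above all WT libraries in 8 of 8 tested neutrophil genes. These 8 genes move together and are not independent. KO replicates 2 and 3 are also very alike (biological coefficient of variation 2.9%). A lower share of T cells with all other types raised alike is argued against by the gap between B cell markers (median log2 fold change -0.517, SD 0.342) and neutrophil genes (3.453, SD 0.878). The sign of the B cell median rests on WT replicate 1, without which it was 0.412 (SD 0.233), but the gap to neutrophil genes (4.404, SD 1.642) stayed. These SDs are between the genes of a list, which move together, and do not measure the spread between libraries. Per library, neutrophil and mast cell markers summed to 13.0 to 36.2 CPM in WT and 85.8 to 310 CPM in KO. B cell markers summed to 128 to 342 CPM in WT and 174 to 213 CPM in KO. Neutrophils or monocytes among the sorted cells or in their RNA cannot be told apart from expression by the T cells themselves after Dlst deletion. Sums over sorted cells hold no cell types. The sort on CD4, FoxP3-GFP and tdTomato is meant to remove such cells, but B cell markers still summed to 128 to 342 CPM per library. How complete the removal was is not known here. For the neutrophil genes, 1 level per library explained 86.5% of the variance, against a 95th percentile of 26.1% in random lists. That share mixes their shared difference between groups with differences between libraries of a group, so it cannot decide.

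Dlst mRNA was 16.6% lower in KO over all its exons. The order of the libraries gave no sign of a mislabelled one, since the lowest WT library lay 19.9 CPM above the highest KO library. This cannot settle the labels, because Dlst did not pass and 22.8% of tested genes had no overlap between groups. Reads from exons outside the deleted part, or cells without the deletion, may keep the level high, and these cannot be told apart from values over the whole gene. No other biological explanation was tested.

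The real split of the 6 samples gave 58 genes higher and 28 lower, each the largest of 10 splits (1 of 10), and the highest of the other splits gave 1 gene. For lists, 5 of the 10 splits gave at least as many as the real 14, the highest of the others 17. These 10 splits are too few for a share under 0.05.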
